A study of Drosophila melanogaster with 30 samples.

How the data were processed

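RNA-seq libraries came from HWT and H4K16R wing discs of both sexes (3 per group; 12 in all) and Repli-seq libraries from 6 genotype and sex combinations (2 S-phase and 1 G1 library each; 18 in all), grouped by the titles of the samples. The labels name separate replicates but not separate animals or crosses, so p-values measure the spread between these libraries. Per the labels' protocols, RNA libraries were stranded, depleted of ribosomal RNA and spiked with ERCC controls. The submitters' processing notes name TopHat, Cufflinks 2.2.1, edgeR, Bowtie2 2.3.2, SAMtools 1.6, bedtools and limma and the build dm6, without a role for each.

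The RNA files are the authors' own comparisons. Per the file headers, the authors deposited a log2 fold change and an adjusted p-value for each genomic interval from edgeR, 1 table per sex, with no expression level, count or value per library. The numerator is not stated and was read as H4K16R over HWT, and the adjustment method is not stated and was taken as Benjamini-Hochberg. The authors deposited replication timing as 1 value per group in windows of 100 kb that start every 10 kb, except that the yw file gives 10 kb bins. In the H4K16R female table these deposited values are a linear S/G1 ratio, centred near 1, and log2 was taken here; in the other timing tables the deposited values are centred near 0 and were read as log2, a base the headers do not state. How the authors combined the S-phase replicates, and how the HWT profile came to differ between the 2 female tables, is not given in the sources used here. Timing differences are therefore differences of the authors' values, without a p-value, SD or n.

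Planned per-library models were replaced by what the deposited units allow. Gene names were given to intervals that overlapped a RefSeq gene of Release 6 reciprocally by more than 0.9; 9345 of 10775 female entries (86.7%) and 9565 of 11505 male entries (83.1%) got one name. Overlapping entries share reads and cannot be told apart: 5993 female and 6683 male entries overlap another, and the fold changes of overlapping pairs correlated at 0.599 and 0.698. Unadjusted p-values were recovered as adjusted p times rank over the number of entries, and standard errors from the fold change and the recovered p; tied adjusted p make the recovered p an upper bound within each tie. Male and female effects were compared by a z test of their difference with Benjamini-Hochberg adjustment. Gene lists, 30 in number, and location lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the recovered signed statistic with a preset inter-gene correlation of 0.01, in lists with at least 3 measured genes. An estimated correlation needs per-library values and could not be had. Shares of called entries were compared with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg within each family; entries were also joined into loci where they overlapped each other or the same annotated gene. The interval of the X minus autosome median is a 95% bootstrap over entries with 2000 draws. Timing windows with an absolute difference of at least 0.1 on the log2 scale were counted as shifted. Pericentromeric blocks were 2L from 22 Mb, 2R to 6 Mb, 3L from 23 Mb, 3R to 4 Mb and X from 22 Mb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

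The steps were tested on simulated data. With the female and male tables' standard errors, 60% of genes changed by 1 on the log2 scale were called in both, and 48% and 30% of those changed by 0.5; unchanged genes were called at 0.0473% in the simulated female table and 0.0796% in the male one. The difference test called 2.09% and 1.01% of unchanged genes at an unadjusted p under 0.05. Its second simulated table held no changed genes and had the same standard errors as the first. This low rate therefore need not hold for the deposited tables. A planted timing difference of 0.1 was counted in 60.4% of windows and one of 0.2 in 98.9%.

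Before the data were examined, the comparisons, gene lists, alternatives and the rule for named genes were fixed. The rule takes the 10 highest and 10 lowest called genes per RNA comparison, called members of the lists (up to 4 examples each, by size), the MSL genes, roX1, roX2, His4r, p53, the Orc and Mcm genes, and per timing comparison the 5 strongest merged runs per direction, the histone cluster, Ubx and Antp. It was applied to entries with a gene name, and entries without one are described apart. Alternatives were a stricter adjusted p, minimum fold changes, Holm adjustment, other list settings, larger timing differences, non-overlapping windows, other scalings, moved block boundaries and exclusion of heterochromatin. Windows on the Y, on unplaced scaffolds and on the mitochondrial genome were kept out of the timing comparisons.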

Results

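Wing imaginal discs, the larval epithelia that give rise to the adult wing, were profiled from third-instar Drosophila melanogaster whose endogenous replication-dependent histone genes had been deleted and replaced by a transgene of 12 histone repeats of 5 kb each. The transgene carried wild-type histone genes (HWT), histone H4 with lysine 16 changed to arginine (H4K16R), or histone H3 with lysine 9 changed to arginine (H3K9R). H4K16R cannot be acetylated at a residue that the male-specific lethal (MSL) complex acetylates along the single male X chromosome during dosage compensation, and H3K9R cannot be methylated at a residue that marks pericentromeric heterochromatin. RNA was sequenced from HWT and H4K16R discs of both sexes, with 3 libraries per group and 30 discs per library. Replication timing was measured by Repli-seq, in which nuclei are sorted by DNA content and the coverage of S-phase DNA is divided by that of G1 DNA, so that a high S/G1 value marks early replication. Each timing group had 2 S-phase libraries and 1 G1 library, for HWT and H4K16R of both sexes, for H3K9R females and for females of the yw strain, which keeps its own histone genes. The files used here give 1 value per gene or window for each comparison or group, so the depth of single libraries is unknown and no spread between replicates could be computed.

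The comparison of H4K16R with HWT in males asks how RNA levels depend on H4K16 in the sex that acetylates its X. X-linked genes were lower in H4K16R males across the chromosome. In the authors' deposited table of males, 1797 of 11505 entries had an adjusted p under 0.05, of which 616 were higher and 1181 lower in H4K16R. The lower entries comprised 847 of 1901 X-linked ones and 321 of 9472 on the large autosomes 2 and 3 (odds ratio 22.9), by the adjusted p of the authors' deposited table. Higher entries made up 22 of the X-linked and 577 of the autosomal set of the authors' deposited table (odds ratio 0.181, Fisher's exact test over entries, adjusted p = 2.07e-23). The median log2 fold change in the authors' deposited table was -0.43 for the X and 0.08 for the autosomes, and 85.5% of X-linked entries lay below 0. The difference of the medians was -0.51 on the log2 scale, a ratio of 0.703, with a bootstrap interval over entries from -0.53 to -0.49. Each of 24 bins of 1 Mb along the X had a median below 0, between -0.57 and -0.23, in the authors' deposited table. These tests run over genes, which are not replicates, and the table does not state which genotype is the numerator, which is taken as H4K16R throughout.

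**Figure D1:**
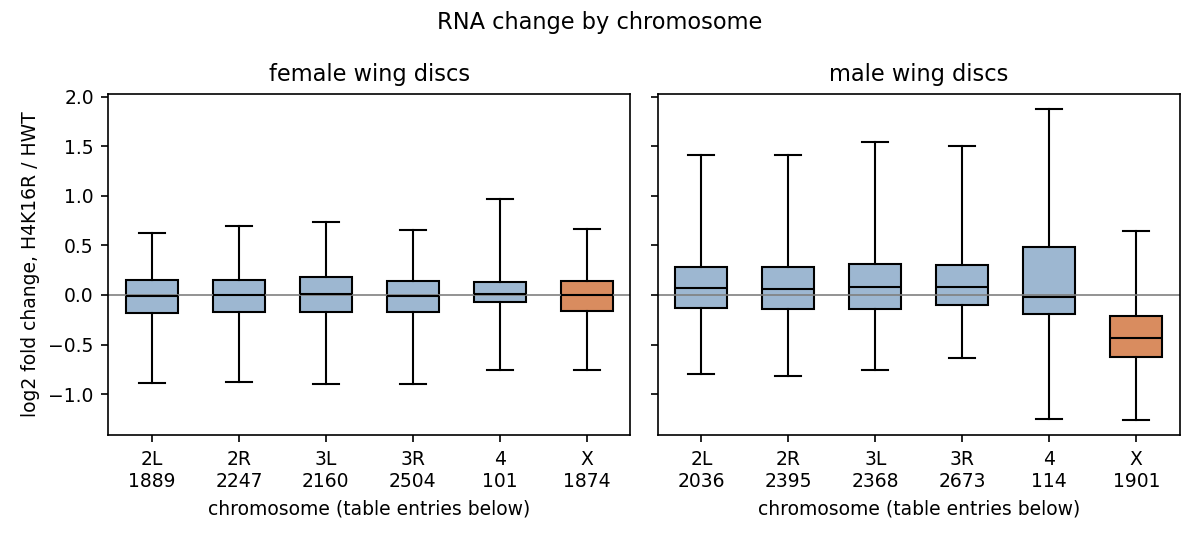
Log2 fold change of RNA, H4K16R over HWT, for entries of the authors' deposited tables by chromosome, in females (left) and males (right). Boxes span the quartiles with the median as a line, whiskers reach the 5th and 95th percentiles, and the number of entries stands under each chromosome; the male X box (orange) is centred on -0.43.

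X-linked members of the dosage compensation machinery were lower as well. In the authors' deposited table of males, mof, which encodes the H4K16 acetyltransferase of the MSL complex, fell by 0.43 on the log2 scale (adjusted p = 0.0041). The 2 X-linked noncoding RNAs of the complex, roX1 and roX2, had log2 fold changes of -0.27 (adjusted p = 0.0097) and -0.44 (adjusted p = 0.023) in the authors' deposited table. The autosomal genes msl-1, msl-2, msl-3 and mle had values of 0.07, 0.09, 0.11 and 0.07 in the authors' deposited table and did not pass. His4r, a replication-independent histone H4 gene outside the cluster, had 0.01 (adjusted p = 0.97), and p53 had 0.01 (adjusted p = 0.98), in the authors' deposited table. X-linked replication genes were among the lower ones: Psf3, a subunit of the GINS complex, had -1.11, the helicase cofactor Cdc45 -0.82, and the helicase subunits Mcm3 and Mcm6 -0.73 and -0.51, in the authors' deposited table. The autosomal Mcm2, Mcm5, Mcm7, Mcm10 and dpa and the origin recognition genes Orc1, Orc2, Orc5 and Orc6 lay between -0.10 and 0.28 in the authors' deposited table, none of them past the threshold. Of 24 origin licensing genes, 5 were lower and 0 higher in the authors' deposited table, with the same counts adjusted over the list alone. Of 20 replication fork genes, 2 were lower and 1 higher, again with the same counts. Neither list passed (camera, adjusted p = 0.30 and 0.997). Sxl, the X-linked switch gene of sex determination, fell by 0.59 (adjusted p = 1.09e-05), and the neuronal gene elav by 1.03 (adjusted p = 4.78e-07), in the authors' deposited table.

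The lists of p53 targets and of heat shock genes ranked higher in H4K16R males. Of 20 measured p53 targets and apoptosis genes, 9 were higher and 2 lower over all genes in the authors' deposited table, and 10 were higher and 4 lower adjusted over the list alone. The list ranked higher than other genes (camera with a preset correlation of 0.01, adjusted p = 0.0028). The p53-induced transcription factor Xrp1 rose by 1.54 on the log2 scale (adjusted p = 9.3e-11) in the authors' deposited table. Its dimer partner Irbp18 rose by 1.08, and the Ku subunits of double-strand break repair, Ku80 and Irbp, by 1.31 and 1.10, with adjusted p between 4.24e-05 and 3.86e-04 in the authors' deposited table. The lower members were the cell death activator rpr (-0.92) and the receptor gene grnd (-0.52), named after their values in the authors' deposited table were seen. Of 23 DNA damage genes, 4 were higher and 2 lower in the authors' deposited table, and 5 and 2 adjusted over the list alone (camera, adjusted p = 0.029, lost at a preset correlation of 0.05 with adjusted p = 0.16). PolZ1, the catalytic subunit of translesion polymerase zeta, rose by 0.80 and the excision repair gene Xpc by 0.54, in the authors' deposited table. The X-linked mei-41 and Xpac had -0.66 and -0.52 in the authors' deposited table. Of 16 heat shock and chaperone genes, 5 were higher and 1 lower in the authors' deposited table (11 and 2 adjusted over the list alone; camera, adjusted p = 0.0037). Hsp70Ba had 1.68, CG4456 1.66 and Hsp26 0.69 in the authors' deposited table, and Hsp23 fell by 0.42. The small heat shock gene l(2)efl went the other way more strongly, at -4.15 (adjusted p = 0.034) in the authors' deposited table. Hsp70Ba has near-identical copies that share reads, so its value is uncertain.

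Wing patterning genes ranked slightly lower in H4K16R males. Of 42 measured, 9 were lower and 0 higher in the authors' deposited table (13 and 0 adjusted over the list alone), with a median of -0.13 (camera, adjusted p = 0.0034). That call was lost at a preset correlation of 0.05 (adjusted p = 0.072) and kept with autosomal genes only (adjusted p = 2.65e-04). The X-linked selector genes ct and sd had -0.48 and -0.33 in the authors' deposited table, where the X median was -0.43. The paired vein genes kni and knrl, on 3L, had -0.37 and -0.35 in the authors' deposited table. Of the 42 measured genes, 9 lie on the X. Markers of adult muscle precursors, which lie beneath the disc epithelium, had 4 lower and 1 higher of 23 in the authors' deposited table, with the same counts adjusted over the list alone (camera, adjusted p = 0.019, and 0.13 at a preset correlation of 0.05). Mlc2 had -1.37 and Ama -0.41 in the authors' deposited table, while kirre rose by 0.31.

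Fat body markers ranked lower in H4K16R males by camera over all chromosomes, while markers of 2 other larval tissues did not pass. With the rank-based form of that test, salivary gland glue genes passed (adjusted p = 0.043). Fat body markers (0.068) and hemocyte markers (0.17) did not. Of 12 measured fat body markers, 7 were lower and 1 higher in H4K16R males in the authors' deposited table (8 and 2 adjusted over the list alone), with a median of -2.08 (camera, adjusted p = 0.019, and 0.072 at a preset correlation of 0.05). The larval serum protein genes Lsp1alpha and Lsp1gamma had -2.88 and -2.79 and the apolipophorin gene apolpp -2.69 in the authors' deposited table. Salivary gland glue genes had a median of -3.04 over 6 genes in the authors' deposited table, with 0 called over all genes and 0 adjusted over the list alone (camera, adjusted p = 0.14, and 0.0081 with autosomal genes only). Hemocyte markers had a median of -0.39 over 14 genes with 0 called in the authors' deposited table (0 adjusted over the list alone; camera, adjusted p = 0.46, and 0.042 with autosomal genes only).

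The largest male fold changes of named genes came with wide errors. In the authors' deposited table the 10 highest named genes were CG8620 (7.44), CG13033, CG31327, the dopamine transporter gene DAT (7.04), snRNA:U5:38ABb (6.86), snRNA:U2:38ABa (6.68), CG14853, the tachykinin receptor gene TkR86C (6.27), Phlpp and ppk17 (6.13). Their adjusted p in the authors' deposited table lay between 0.0012 and 0.036, and the tables give no expression level to show how far these genes lie above the detection floor. The spliceosomal snRNA genes have near-identical copies, and their values are uncertain. The 10 lowest named genes in the authors' deposited table were CG33346 (-6.42), CG12115, CG1503, CG15818, the small heat shock gene l(2)efl (-4.15), CG15044, the kinetochore gene Nnf1b (-2.99), Lsp1alpha, Lsp1gamma and apolpp (-2.69). The highest value of all, 9.10 (adjusted p = 2.85e-06) in the authors' deposited table, belonged to a pair of overlapping entries without a gene name at 2L:21554357-21554714 (dm6, chosen after its value was seen), beside the histone gene cluster. With names left aside, 54 entries of the authors' deposited table were higher by at least 4 on the log2 scale, 17 of them in pericentromeric blocks, including 7 of the gene Myo81F. On the large autosomes, 36 of 346 pericentromeric entries were higher against 541 of 9126 in the arms in the authors' deposited table (odds ratio 1.84, Fisher's exact test, adjusted p = 0.0053). This call was lost with each locus counted as 1 (26 of 271 against 472 of 5725, odds ratio 1.18, adjusted p = 0.65) and with named entries only (12 of 138 against 470 of 7770, odds ratio 1.48, adjusted p = 0.42), in the authors' deposited table. Chromosome 4, a small heterochromatin-rich autosome, had 13 of 114 entries lower against 321 of 9472 on the large autosomes in the authors' deposited table (odds ratio 3.67, adjusted p = 7.2e-04). Another 9 were higher and the median was -0.02 in the authors' deposited table, and the chromosome did not pass as a location list (camera, adjusted p = 0.54). Of 18 Y-linked entries, 8 were higher in the authors' deposited table (odds ratio 12.3, adjusted p = 3.01e-05), among them FDY at 3.43. The list of Y-linked genes did not pass: of 4 measured, 1 lay above 0 and 1 was higher in the authors' deposited table (1 adjusted over the list alone), with a median of -0.59, a mean of 0.32 and a test pointing up (camera, adjusted p = 0.81). The 8 named genes on the Y, tested as a location list, ranked higher (adjusted p = 0.019, and 0.065 at a preset correlation of 0.05).

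The same comparison in females changed far fewer genes. In the authors' deposited table of females, 105 of 10775 entries passed an adjusted p of 0.05, with 39 higher and 66 lower in H4K16R, while 1252 had a recovered unadjusted p under 0.05. The median log2 fold change of X-linked entries differed from that of autosomal ones by 0.003 on the log2 scale (bootstrap interval -0.013 to 0.016) in the authors' deposited table, and 13 of 24 bins of the X lay below 0. The MSL genes, His4r, p53 and the Orc and Mcm genes did not pass in the authors' deposited table of females. The potassium channel gene SK, at X:5340236-5405138 (dm6), had the lowest value among called genes, -4.11 (adjusted p = 2.61e-08) in the authors' deposited table. The other lowest named genes in the authors' deposited table were lncRNA:CR44619 (-3.29), CG31098, Gip (-2.81), CG17036, the serpin gene Spn42De (-2.37), the methyltransferase gene Bhmt, the transporter gene Abca3, the aldehyde dehydrogenase gene Aldh and CG7054 (-1.63). The highest named genes in the authors' deposited table were the cuticle gene Cpr56F (2.51), CG46523/CG5687 (2.05), Vajk4 (1.86), the small-peptide gene tal-1A/tal-2A/tal-3A/tal-AA (1.24), Cadps (0.89), Cpr49Ac, CG15784 (0.83), CG4382, the ecdysone-inducible ImpE3 (0.78) and lncRNA:CR43264. A pair of overlapping entries without a gene name at 2R:1632005-1632390 (dm6, chosen after their values were seen) had 7.51 and 7.45 in the authors' deposited table.

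Several gene lists ranked higher than other genes in females, with few members called singly. Ribosomal protein genes had a small shift, with 70 of 76 above 0 and a median of 0.14 in the authors' deposited table (camera, adjusted p = 1.82e-10), although 0 were called singly and 0 adjusted over the list alone. Wing patterning genes had 38 of 43 above 0 and 0 called in the authors' deposited table (0 adjusted over the list alone; adjusted p = 1.13e-04). Cuticle genes had 30 of 41 above 0 and 2 called higher in the authors' deposited table (6 adjusted over the list alone; adjusted p = 2.87e-04). Ecdysone response genes had 18 of 28 above 0 and 3 called higher in the authors' deposited table (4 higher and 1 lower adjusted over the list alone; adjusted p = 4.83e-04), namely ImpE3, ImpE2 (0.58) and Eip78C (0.50). Tracheal markers had 0 called of 13 in the authors' deposited table (4 higher adjusted over the list alone; adjusted p = 0.012, and 0.057 at a preset correlation of 0.05).

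Cell cycle and replication lists ranked lower in females. Of 34 cell cycle and mitosis genes, 6 lay above 0 and the median was -0.16 in the authors' deposited table (camera, adjusted p = 9.37e-07), with 1 lower over all genes and 6 adjusted over the list alone. The called member was the spindle kinesin gene ncd, at -0.55 in the authors' deposited table. Origin licensing genes had a median of -0.20 over 24 genes in the authors' deposited table (adjusted p = 5.15e-05), with 0 called and 0 adjusted over the list alone. Replication fork genes had a median of -0.12 over 21 genes and histone variants and chaperones of -0.12 over 19 in the authors' deposited table, with 0 called and 0 adjusted over the list alone. Their adjusted p were 0.014 and 0.019, and 0.077 and 0.089 at a preset correlation of 0.05. DNA damage genes had 1 lower of 26 in the authors' deposited table, the mismatch repair gene Msh6 at -0.52 (3 lower adjusted over the list alone; adjusted p = 0.0077, and 0.066 at a preset correlation of 0.05). Germline genes had 2 lower of 18 in the authors' deposited table, the piRNA pathway genes krimp (-1.41) and nxf2 (-0.92), with 3 lower adjusted over the list alone (adjusted p = 6.32e-04). Fat body markers, of another larval tissue, had a median of -0.82 over 13 genes in the authors' deposited table (1 lower, FASN1 at -1.13, and 1 adjusted over the list alone; adjusted p = 0.017, and 0.066 at a preset correlation of 0.05).

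The H4K16R effect differed between the sexes mainly on the X. Of 8854 genes named in both tables, 699 differed by the z test of male minus female log2 fold changes, with standard errors recovered from the authors' deposited tables. On the X, 386 genes were lower in males than in females by this test and 9 higher, and on the large autosomes 115 were lower and 182 higher. The median male minus female difference was -0.438 on the X and 0.0743 on the large autosomes. These counts were made without removing that autosomal offset. With each sex centred on its autosomal median, 981 genes differed. Calls in the authors' deposited tables overlapped more than independent lists would, with 7 genes higher in both (1.59 expected, Fisher's exact test, p = 7.85e-04) and 28 lower in both (6.78 expected, p = 6.84e-12). The 4 genes called in opposite directions in the authors' deposited tables were stw, Cadps, Snap25 and rdog. For the potassium channel gene stw the values were 0.55 in females and -0.60 in males, and for Cadps 0.89 and -0.75, in the authors' deposited tables. Snap25, of the synaptic fusion machinery, had -0.68 in females and 2.14 in males, and rdog -1.23 and 1.87, in the authors' deposited tables.

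The timing comparison of H3K9R with HWT females asks whether H3K9 sets late replication of heterochromatin. Few windows passed the cut: 298 of 13389 windows of 100 kb (2.23%) shifted by at least 0.1 on the log2 scale. Of these, 192 were earlier and 106 later (271 earlier and 275 later against the HWT profile of the H4K16R female table). The profiles correlated across windows with r = 0.912. The interquartile range of HWT was 0.122, so windows under this cut may still have shifted. Of the 192 earlier windows, 163 lay in pericentromeric blocks. The autosomal pericentromeric blocks replicated earlier on average by 0.0243 in H3K9R, and the block of 3R by 0.0528. Against the HWT profile of the H4K16R female table, which comes from the same HWT group, these differences were 0.00637 and 0.0696, so the 3R value persisted and the autosomal mean did not. The blocks of 2L, 2R, 3L and X, earlier in H3K9R against the HWT of their own table, turned to -0.00437, -0.00568, -0.0249 and -0.00891, and the autosomal blocks then held 196 earlier and 132 later windows. Chromosome 4 was earlier by 0.0400, and by 0.0295 against the other HWT profile. The strongest earlier runs lay at 3R:1840001-2310000 (mean difference 0.159) and X:21730001-22530000 (0.157), and the strongest later run at X:2700001-2930000 (-0.179), on dm6. With one value per group these shifts have no replicate test, and 2 versions of the same HWT group differed by over 0.1 in 1.47% of windows once their offset was removed. The SD of that difference was 0.0698 in pericentromeres and 0.0193 in arms. Counts of shifted female windows therefore lean towards pericentromeres even with no change of genotype.

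**Figure D2:**
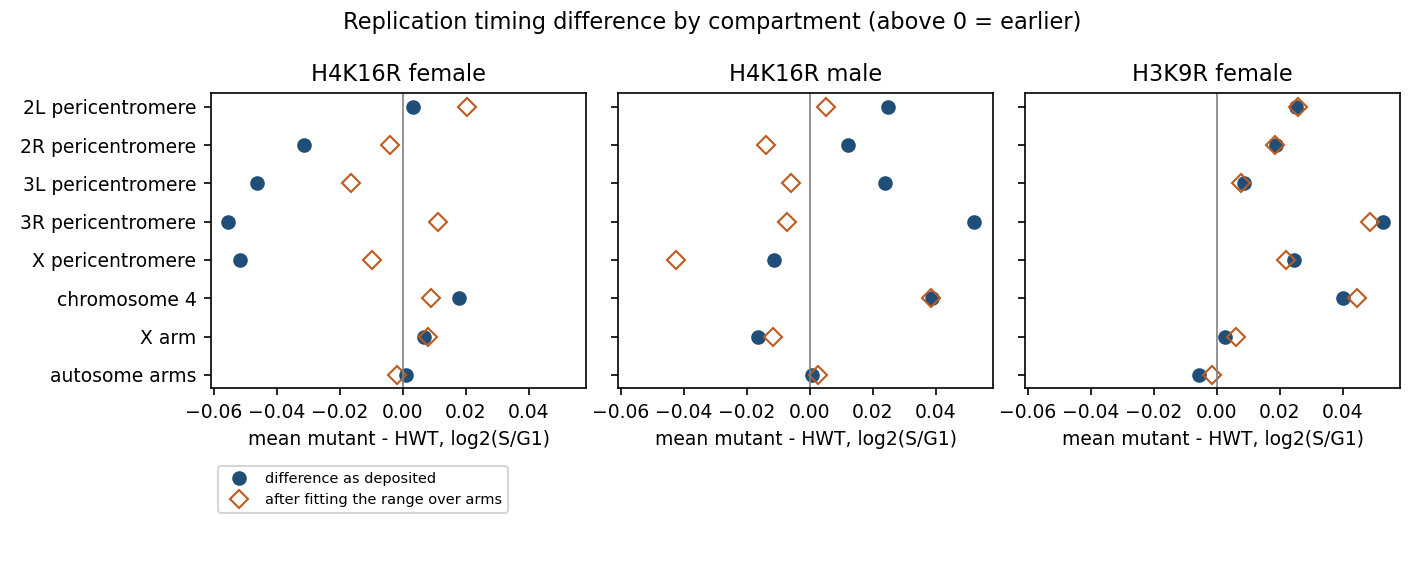
Mean mutant minus HWT replication timing, log2(S/G1), per compartment in the 3 comparisons; values above 0 are earlier in the mutant. Filled circles are differences as deposited and open diamonds are residuals from the line of mutant on HWT over arm windows; the 3R pericentromere lies at 0.0528 in H3K9R females and 0.0522 in H4K16R males before this correction, and at 0.0485 and -0.00736 after it.

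In H4K16R males, 245 of 13293 windows (1.84%) shifted by at least 0.1, with 147 earlier and 98 later, and the profiles correlated with r = 0.959. The split was 200 earlier and 66 later with each profile centred on its median, and 25 and 97 as residuals from the line of mutant on HWT over the arms. Of the earlier windows, 128 were pericentromeric. The autosomal pericentromeric blocks were earlier by 0.0266 and that of 3R by 0.0522, and both values fell to -0.00815 and -0.00736 when the smaller range of the mutant profile was fitted over the arms. With equal interquartile ranges they were 0.0193 and 0.0360. The 2 corrections therefore differ in sign. Chromosome 4 was earlier by 0.0387, and by 0.0385 after the fit over the arms. The X arm replicated later in the mutant by 0.0164 on average (mean difference -0.0164), with 63 windows later and 3 earlier, while the autosome arms differed by 0.000595. The strongest earlier run lay at 3R:1880001-2260000 (0.168) and contained 11 RNA entries, 7 of them higher in the authors' deposited table and all 7 within the gene Myo81F. Whether reads map uniquely in this stretch was not checked. The 5 strongest later runs were 2R:2320001-2460000 (-0.138), X:22790001-22910000 (-0.131), X:20320001-20500000 (-0.127), X:21840001-22030000 (-0.126) and X:1710001-1890000 (-0.125). In this order they held 0, 3, 12, 0 and 14 RNA entries, of which 0, 2, 5, 0 and 12 were called in the authors' deposited table.

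In H4K16R females, 367 of 13389 windows (2.74%) shifted, with 104 earlier and 263 later, and the profiles correlated with r = 0.889. The split was 207 earlier and 276 later against the other HWT profile, 142 and 122 as residuals from the arm line, and 210 and 20 with equal interquartile ranges, so its direction depends on the scaling. The later windows included 200 in pericentromeric blocks, and the autosomal blocks were later on average (mean difference -0.0384). This delay came with a wider range of the mutant profile, whose interquartile range was 1.47 times that of HWT, and the mean residual after fitting the range over the arms was -0.00199, from -0.0164 in 3L to 0.0204 in 2L. The means of these 2 blocks include the extreme runs named next, and their median residuals were -0.0164 in 3L and -0.00853 in 2L. The strongest earlier run was 2L:22790001-22900000 (mean difference 1.85) and the strongest later run 3L:27470001-27580000 (-1.12), each of 2 windows. Both overlap runs of the opposite sign, 2L:22760001-22870000 (-0.169) and 3L:27440001-27600000 (0.119), and the HWT value of the 3L run was 0.819 inside a late block, so these extremes are uncertain. At the histone gene cluster, 2L:21416953-21541681, the window 2L:21430001-21530000 had an S/G1 ratio of 2.88 in H4K16R against 1.10 in HWT, and the differences of the 23 windows that touch the cluster ranged from -0.0756 to 1.51 on the log2 scale, with a mean of 0.231. The endogenous cluster is deleted in these animals, so values over it cannot be read as timing of the 2L locus. The origin of the reads there was not tested, and neither was mappability. In H3K9R females the same window had a ratio of 1.01 against 1.00 in HWT. In H4K16R males, with 14 windows touching the cluster, the window 2L:21390001-21490000 had 1.02 against 0.970. At the homeotic genes, the window of Ubx differed by -0.0713 in H4K16R females and -0.0571 in H3K9R females, and that of Antp by 0.0322 and 0.0167. In males they differed by -4.79e-05 and 0.0269.

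**Figure D3:**
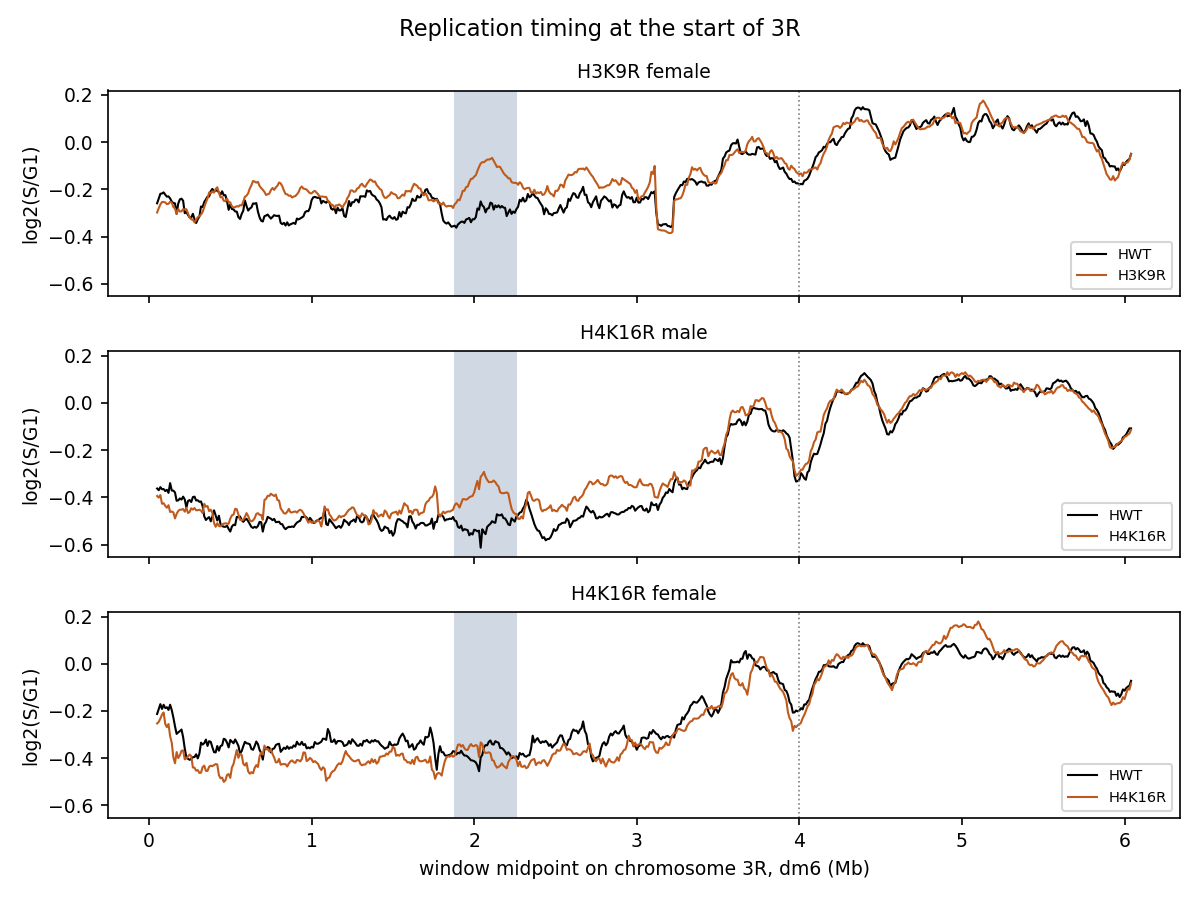
Replication timing, log2(S/G1), of HWT (black) and mutant (orange) discs against window midpoint at the start of 3R (dm6, Mb) in the 3 comparisons. The shaded stretch is 3R:1880001-2260000, where the mean difference was 0.170 in H3K9R females, 0.163 in H4K16R males and -0.0107 in H4K16R females; the dotted line is the pericentromere boundary used here, at 4 Mb.

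Shifted windows of the comparisons were set side by side. H3K9R females and H4K16R males, which share no control, had 50 earlier windows in common. Since windows overlap, these form 8 stretches, and 27 of the 50 windows lie in 3R:1880001-2260000. H4K16R and H3K9R females shared 25 later windows in 8 stretches and 2 earlier ones. Their differences correlated with r = 0.251 (0.0229 in pericentromeres, 0.476 in arms) and, by ranks, with Spearman's rho 0.417. Independent windows would share 1.85, 2.07 and 1.49, but these windows overlap, so the counts are not a test. Both female comparisons share HWT libraries, and unchanged groups against an identical control would give a simulated r of 0.496. The covariance of their differences was 0.000596. A value of 0.000862 would follow if the smaller of their 2 variances were all error, split equally between mutant and HWT. Both yardsticks assume an identical control, but the 2 HWT profiles used correlated at 0.945. They therefore cannot tell a shared effect from a shared control. H4K16R females and males correlated with r = -0.0842, and H3K9R females and H4K16R males with r = 0.210 (0.388 in pericentromeres, 0.0754 in arms). The yw profile correlated across windows with HWT at r = 0.911 and 0.912 for the 2 female profiles and 0.933 for males.

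RNA and timing changes were then compared, with each RNA entry placed in the 1 window whose centre lies nearest its midpoint. In males, 11 of 24 RNA entries in earlier-shifted windows were higher against 596 of 11392 elsewhere, by the calls of the authors' deposited table (odds ratio 15.3, Fisher's exact test over entries, adjusted p = 2.56e-07). Of these 11 entries, 7 lie within the single gene Myo81F. With entries that overlap each other or the same annotated gene counted as 1 locus, the share was 3 of 11 against 512 of 7122 in the authors' deposited table (odds ratio 4.84, adjusted p = 0.14), and the call was lost. In later-shifted windows 23 of 71 entries were lower in the authors' deposited table (odds ratio 4.23, adjusted p = 2.41e-06; by locus 21 of 54, adjusted p = 4.05e-06). Within the X the share was 21 of 39 against 826 of 1862 in the authors' deposited table (adjusted p = 0.93). In females none of the 55 entries in earlier and 25 in later windows was called in the authors' deposited table; placed by gene start, 1 of 27 in later windows was lower. By the whole extent of merged runs, Msh6, lncRNA:CR44619 and E(spl)malpha-BFM lay in earlier runs and dnc in a later one (named after their values were seen), so the absence of calls depends on the placement. Across windows with at least 3 entries, the timing difference and the median log2 fold change of the authors' deposited tables correlated at Spearman's rho 0.175 in females and 0.170 in males. On autosome arms alone these values were 0.181 and 0.0668, and on the X arm alone 0.174 and 0.223. Early windows held more RNA entries: the number of entries per window correlated with HWT timing across windows at Spearman's rho 0.599 in females and 0.623 in males, windows not being independent replicates.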

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

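All tests of explanations in this part were chosen after the result was seen, except that of extreme fold changes. The H4K16R effect on RNA differed between the sexes for 699 genes, 386 of them X-linked genes with a lower log2 fold change in males, by the test of the difference itself with recovered standard errors. The lower X-linked RNA of males may reflect loss of H4K16 acetylation on the male X. A uniform scaling of libraries moves X and autosomes alike, so it cannot give the X minus autosome median of -0.51. A few extreme entries can hardly move a difference of medians, which stayed at -0.475 with entries of 1 or more in absolute log2 fold change left out. Both outcomes were near fixed by the choice of measure and favour no other explanation. The female difference of 0.0029 is what loss of acetylation on the male X would give. A difference between male libraries other than genotype stays open, since no value per library was at hand.

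Among genes named in the text, the male minus female difference on the log2 scale passed the test upward for snRNA:U5:38ABb (7.94), GstE6 (7.14), lncRNA:CR44619 (4.85), SK (4.24), Cyp6d2 (3.48), CG15784 (3.19), rdog (3.09), Snap25 (2.82), krimp (2.51), CG4456 (2.49), Gip (1.80), FASN1 (1.47), Xrp1 (1.23), Irbp18 (1.18), Ku80 (1.11), PolZ1 (0.99), y (0.79), Xpc (0.65), Msh6 (0.59), Orc1 (0.55) and Mcm2 (0.47). It passed downward for Cadps (-1.64), stw (-1.15), rpr (-1.06), elav (-0.84), Xpac (-0.76), Sxl (-0.74), Cdc45 (-0.72), ImpE3 (-0.63), Hsp23 (-0.60), ct (-0.59), grnd (-0.56), knrl (-0.51) and sd (-0.40). Among gene lists, the camera test on the difference passed for wing patterning (adjusted p = 5.93e-06), ribosomal proteins (0.0032, and 0.12 at a preset correlation of 0.05), tracheal markers (0.0032), muscle precursor markers (0.0034) and X-linked housekeeping genes (0.0077), all lower in males than in females. The housekeeping list lies wholly on the X and is part of the shift of that chromosome. The camera test passed upward for heat shock genes (adjusted p = 1.70e-04), DNA damage genes (0.0010), germline genes (0.0055) and cell cycle genes (0.018, and 0.15 at a preset correlation of 0.05), while the p53 list did not pass (0.094). With autosomal genes only, ecdysone response genes (camera, adjusted p = 0.021, lower in males) also passed. So did H4K16 and NSL complex regulators (0.021) and origin licensing genes (0.035), both higher in males.

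In the male timing table, 46 windows on unplaced scaffolds, outside the comparisons of the report, were earlier in H4K16R by 0.0716 on average, and 40 of them lay above 0. On the Y, 204 windows differed by 0.0494 on average. As residuals from the line of mutant on HWT over the arms these means were -8.79e-05 and -0.0256. The unplaced windows thus lay on that line on average. The Y lay later than the line, with 68 of 204 windows above it. The line was fitted over arm windows only, so range and timing cannot be told apart here.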

How the results depend on the processing

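No paired analysis was possible because the files hold 1 value per comparison or group and no column carries a replicate number. For the same reason, limits on expression level, adjustment of the original p-values, DESeq2, leaving out replicates, other splits of the libraries, timing tests with their adjusted p and trend, and normalization per replicate were not run, and depth could not be assessed. Alternatives using the other HWT profile, the arm line, compartment scaling, autosomal lists, named or merged entries, entries joined into loci, stretches of shared windows, splits of earlier and later windows under each scaling, centring of the sex difference and its threshold of 0.01 were chosen after seeing the data, and so was the rule that counts a compartment difference as moved beyond 1.5-fold. The male X minus autosome difference stayed between -0.56 and -0.47 in all 4 alternatives. Calls fell, by construction of stricter limits, from 105 to 49 in females and from 1797 to 1120 in males at an adjusted p of 0.01, to 45 and 327 at an absolute log2 fold change of 1, and to 18 and 278 with Holm adjustment. At 1.5-fold the male count was 755. The sex difference was called for 310 genes at 0.01, and for 981 with each sex centred on its autosomal median. With a preset correlation of 0.05, 7 of 12 female and 3 of 9 male lists passed. The share of shifted windows fell to 0.194% in H4K16R females, 0.0451% in H4K16R males and 0.105% in H3K9R females at a difference of 0.2, and to 1.28%, 0.841% and 0.962% without pericentromeres and chromosome 4. It was 1.72% in H4K16R females with equal interquartile ranges, 0.918% in H4K16R males as residuals from the arm line, and 4.08% in H3K9R females against the other HWT profile; the cause was not tested. The autosomal pericentromeric difference of H4K16R females (-0.0384) became -0.00199 from the arm line, 0.0317 with equal interquartile ranges and -0.0203 against the other HWT profile. Their 3R difference (-0.0554) turned to 0.0111 and 0.0623 under the first of these settings and the second, and was -0.0722 against the other HWT profile. Their chromosome 4 difference (0.0179) became 0.00904, 0.00674 and 0.0291. In H4K16R males the arm line took the autosomal and 3R pericentromeric differences to -0.00815 and -0.00736, while equal interquartile ranges left 0.0193 and 0.0360. In H3K9R females the autosomal pericentromeric difference was 0.00637 against the other HWT profile. Counting each locus as 1 took the odds ratio of higher entries in earlier male windows from 15.3 to 4.84 (adjusted p from 2.56e-07 to 0.14) by construction, with 11 loci in place of 24 entries. It took that of higher male entries in autosomal pericentromeres from 1.84 to 1.18, and named entries only took it to 1.48; neither passed. For the 4 higher female entries there it went from 4.51 (adjusted p = 0.037) to 3.08 and 2.25, past no threshold. For lower male entries there it was 1.40 (adjusted p = 0.45) over all entries and 2.80 (adjusted p = 0.0069) over named ones. The male calls on the X, chromosome 4 and the Y were kept. Of single genes past the threshold, 56 did not pass at 0.01 and 78 not at an absolute log2 fold change of 1, out of 175. Of list results, 11 no longer passed at a correlation of 0.05; with the rank test 3 no longer passed and 2 newly passed, and with autosomal genes only 2 and 5.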

Other observations

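Tests of the pericentromeric shifts were chosen after the result was seen. Those of the 3R block were chosen before their outcome, except the range correction of its female value and the reading of its range test for each genotype apart. The block itself was picked from these data and not fixed beforehand. Beyond the groups described above, male JNK, JAK/STAT and regeneration genes and detoxification genes held members with large increases in the authors' deposited table. The cytokine gene upd3 had a log2 fold change of 2.42 (adjusted p = 0.0057), GstE6 3.12 (adjusted p = 3.20e-04) and Cyp6d2 2.32 (adjusted p = 8.48e-07) in the authors' deposited table of H4K16R males. Their lists did not pass as groups (camera, adjusted p = 0.79 and 0.87), with 3 higher and 2 lower of 19, and 2 higher and 12 lower of 71, in the authors' deposited table (adjusted over the list alone, 4 and 2, and 3 and 12); for detoxification genes the test pointed down while the median was 0.034. The eye selector gene toy, on chromosome 4, had 4.62 in males (adjusted p = 7.73e-04) in the authors' deposited table. The X-linked pigment gene y had 0.94 (adjusted p = 1.77e-04) in the authors' deposited table, against the direction of its chromosome.

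The pericentromeric timing shifts of the 3 comparisons may in part come from the range of the profiles. In H4K16R females the residual from the arm line was -0.00199 on average, but the blocks went both ways, with median residuals from -0.0164 in 3L to 0.0068 in 3R. The 3L mean (-0.0164) stayed below every arm stretch of its length, but it includes the 2 uncertain windows at 3L:27470001-27580000. Equal interquartile ranges gave 0.0317, so whether a wider profile accounts for the delay stays open. In H4K16R males the arm line left -0.00815 but equal interquartile ranges left 0.0193, so a narrower range and an earlier pericentromere cannot be told apart. In H3K9R females the interquartile range was 1.03 times that of HWT and the slope over the arms 0.971. The profile was thus hardly narrower, and the fit over the arms could change little (residual 0.0229). There the value of 0.00637 against the other HWT profile shows that the processing of HWT could account for the autosomal mean, and loss of H3K9 methylation stays open.

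The block 3R:1880001-2260000, which overlaps the gene Myo81F, was earlier in H3K9R females and H4K16R males, and in males its 11 RNA entries had a median log2 fold change of 5.95 with 7 called higher in the authors' deposited table (1 entry, at 0.18, in females). The block was picked as the strongest earlier run of H4K16R males, so its male difference and male residual are favoured by that choice. Mappability of the block was not checked. Processing of the HWT profile is excluded for H3K9R, whose difference was 0.217 against the other HWT profile. In H3K9R females the residual was 0.164 of a difference of 0.170, but their profile was hardly narrower, so the correction could take away little. A narrower range remains open in H4K16R males, where the residual was 0.0902, between the bounds of 0.05 and 0.1 set for it. For an effect of H4K16R in either sex, the female difference of -0.0107 lay below the bound set against it. That bound ignored the wider female profile. After the range correction, added once the value was known, the difference was 0.0744. The H4K16R female mean was -0.385, against -0.374 in its own HWT profile and -0.293 in the other. That other HWT profile lay 0.0338 higher on average across all windows. The sign of the female value thus depends on the correction, so this also stays open. A hypothesis for follow-up is that heterochromatin at the start of 3R is altered in both genotypes, which per-replicate values could test.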
